A study of Homo sapiens with 6 samples.

How the data were processed

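Gene expression was measured on oligonucleotide microarrays in NCI-H929, a human multiple myeloma cell line, 24 h after electroporation with small interfering RNA (siRNA). Per the labels, 2 arrays came from cells given siRNA against RRM1, 2 from cells given siRNA against RRM2 and 2 from cells given a non-targeting scramble siRNA. RRM1 and RRM2 encode the large and the small subunit of ribonucleotide reductase, the enzyme that makes deoxyribonucleotides for DNA synthesis. Total RNA was copied into biotin-labelled cRNA for hybridization, per the labels' protocols. The labels do not say whether the 2 arrays of a group came from separate cultures. No p-value therefore covers more than these samples, and the spread between them may be technical.

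The values deposited by the authors are log2 signals for 22277 probe sets on each of the 6 arrays. The summary and normalization method is not given in the sources used here. The base of the logarithm was read from the values: the highest signal per array was about 14.4, which as a natural logarithm would stand for a signal of at least 1784290, far beyond a scanner's range. The array medians lay between 6.11 and 6.16, so the arrays had already been brought to a common scale before deposit, and no further scaling was applied for the reported values. The number of arrays, 2 in each group, limits the precision.

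Probe sets were named from the platform annotation. Of the probe sets, 19070 had 1 gene symbol, 1043 had several and 2164 had none listed. No gene was named from a probe set with several symbols. Gene identifiers of 19058 probe sets matched the RefSeq gene table of GRCh38.p14, which was used for names only and changed 0 symbols. No coordinates are given because the genome build behind the probe sets is not given in the sources used here. For each of the 11963 genes with such a probe set, the probe set with the highest mean over the 6 arrays was used, and 4310 of these genes had more than 1. Genes were tested when that mean reached the 40th percentile of all probe sets, a log2 signal of 5.44, which left 7936 genes. RRM2B was not analysed here.

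Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 6 arrays, so that the 3 groups shared an estimate of the spread with 3 residual and 4.61 prior degrees of freedom. The contrasts were siRRM1 against scramble, siRRM2 against scramble and siRRM1 against siRRM2. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and a count with a change of at least 2-fold is given beside it. Standard errors (SE) are those of the moderated fit. All p-values are two-sided. In each contrast the share of genes whose groups do not overlap is set beside the 33.3% that chance gives for 2 arrays against 2.

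Gene lists, 24 in all, were fixed from general knowledge. They covered deoxyribonucleotide supply, p53 targets, DNA damage and repair, DNA replication, G1/S regulators, G2/M and mitosis, histones, apoptosis, MYC and nucleolar targets, the unfolded protein response, the ATF4 stress response and plasma cell identity. The others were interferon response, NF-kappaB targets, cholesterol synthesis, immediate early and heat shock genes, oxidative phosphorylation, glycolysis, ribosomal proteins, reference genes and markers of T cells, myeloid, epithelial and stromal cells. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 24 lists of a contrast. That test sets the list against all other genes, so its p measures the spread across genes and not between arrays. The same test with an estimated correlation, and the rotation test fry, were alternatives. By fry the p53 targets had an adjusted p of 0.00127 in siRRM1 and 0.00918 in siRRM2 against scramble. Between the knockdowns it was 0.0102, and no other list was under 0.05 there. The G2/M list had fry adjusted p of 0.184 and 0.319 against scramble, and DNA replication 0.0553 and 0.654. The reference genes were under 0.05 by fry (0.0176 and 0.0366). With an estimated correlation, 0 of the lists kept an adjusted p under 0.05 in any contrast, so the p with an estimated correlation stands beside each list called. Members past the threshold were counted over all genes tested and adjusted over the list alone.

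The named genes follow a rule. It takes RRM1 and RRM2, the 10 largest rises and 10 largest falls in each knockdown (5 between the knockdowns) among called genes whose arrays do not overlap, up to 2 risen and 2 fallen members of each list with the smallest adjusted p, or the 2 with the smallest p where none passed, and MYC, CDKN1A, MDM2 and MKI67. A gene named outside this rule is marked as chosen after its values were seen. The groups, contrasts, tests, lists, naming rule and alternatives were set before the data were examined. The exceptions, chosen after seeing the data, were 5 additional lists of leukocyte transcripts, the fit of probe sets without a single gene name, and the tests of explanations that are named as such where they are reported. Members of the additional lists of abundant transcripts were tested in the fit without the filter on dim genes.

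Alternatives to the main settings were quantile normalization, median centring, no filter or a 60th percentile filter on dim genes, the mean of a gene's probe sets, every probe set tested by itself, eBayes with a trend, robust eBayes, a fit over the 4 arrays compared, the replicate number as a block, adjusted p under 0.01 or 0.1, and leaving out each array in turn. Because both knockdowns were compared with the same scramble arrays, their agreement was set beside 100 simulations of unchanged groups against shared controls. The steps were tested on simulated data for siRRM1 against scramble with 7936 genes, of which 200 were changed, in 20 simulations. Log2 changes of 0.5 were recovered in 69.7% of cases and changes of 1 in 99.6%, while 6.01% of the calls were false. In the simulated contrast with no change, a mean of 0.30 genes were called, and 3 of 480 list tests without a change were called. In all these simulations, also those of agreement, every gene varied independently. False list calls among correlated members were therefore not tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.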

Results

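The series measured how loss of each subunit of ribonucleotide reductase changed gene expression in NCI-H929 myeloma cells. There were 6 arrays, 2 each for the scramble control, siRRM1 and siRRM2 groups, all taken 24 h after electroporation. Over the 7936 genes tested, the replicates correlated at r = 0.994 in scramble, 0.993 in siRRM1 and 0.996 in siRRM2. These correlations run across genes, which are not independent replicates. SiRRM1 replicate 1 correlated with both siRRM2 arrays at r = 0.994 and 0.995, and siRRM1 replicate 2 correlated with them at r = 0.988 and 0.992. The siRRM1 replicate 2 array had a median log2 difference of 1.25 between the 3′ and 5′ probe sets of 9 control transcript sets, against 0.83 to 0.95 on the other arrays. In 7 of the 9 it was the highest array. Its ACTB value of 0.33 lay below the 0.34 of scramble replicate 1, and GAPDH was level with that array (-0.013 and -0.017).

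Each siRNA lowered its own target. RRM1 (probe set 201477_s_at) fell by 2.63 on the log2 scale in siRRM1 cells (SE 0.26, limma adjusted p = 0.00154), leaving 22.4% and 11.7% of the scramble mean in the 2 arrays. The other RRM1 probe set gave 24.3% and 11.1%. RRM2 (201890_at) fell by 1.79 in siRRM2 cells (SE 0.25, adjusted p = 0.0214), leaving 21.2% and 39.6%. The other RRM2 probe set, 209773_s_at, gave 12.8% and 18.5%. Neither knockdown changed the transcript of the partner subunit past the threshold. RRM1 had a log2 difference of 0.16 in siRRM2 (adjusted p = 0.780) and RRM2 of 0.24 in siRRM1 (adjusted p = 0.553). The call for RRM2 in siRRM2 was lost without scramble replicate 1 (adjusted p = 0.0748) or scramble replicate 2 (adjusted p = 0.0557), with log2 values of -1.79 and -1.78.

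**Figure D1:**
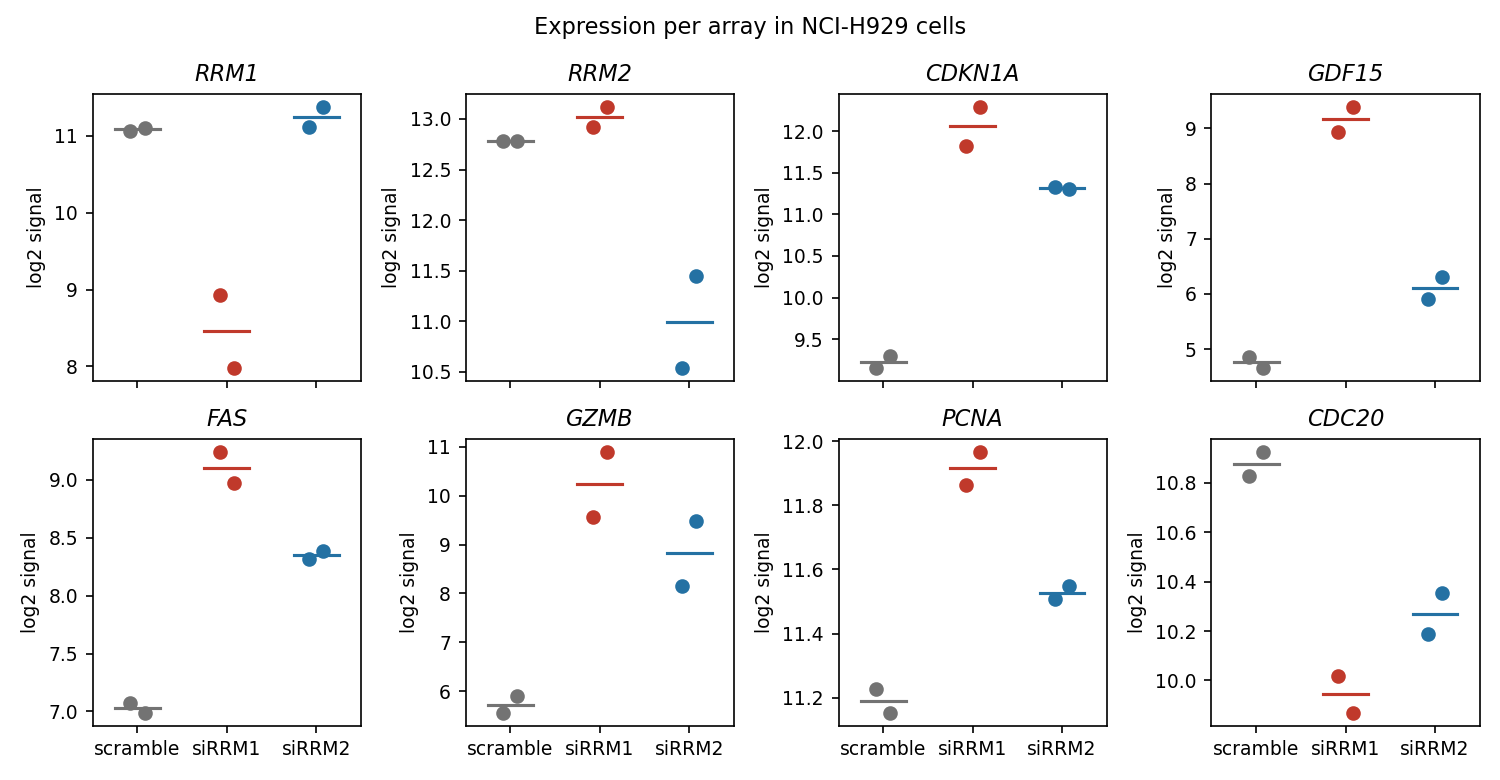
Deposited log2 signal of 8 genes on each of the 6 arrays, with a vertical axis of its own for every gene. Points are arrays and horizontal lines are group means. RRM1 was low in siRRM1 alone (log2 change of -2.63) and RRM2 in siRRM2 alone (-1.79), while CDKN1A lay above scramble in both knockdowns (2.83 and 2.09).

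The comparison of siRRM1 with scramble asked what loss of the large subunit does to expression. The largest rises were in GZMB, the cytotoxic granule protease granzyme B, and GDF15, a stress-induced cytokine. GZMB rose 22.7-fold (log2 4.50, SE 0.50, adjusted p = 0.00237) and GDF15 rose 21.2-fold (log2 4.40, SE 0.19, adjusted p = 8.43e-05). The cyclin-dependent kinase inhibitor CDKN1A rose 7.12-fold (log2 2.83, SE 0.15, adjusted p = 1.80e-04). Rises also included S100A8, a calcium-binding protein of myeloid cells (log2 4.23), the cytokines IL10 (3.64) and IL17A (3.24), and LAPTM5, a lysosomal membrane protein of blood cells (3.53). The antisense transcript DTNB-AS1 (3.22), the matrix glycoprotein TNC (2.71) and the chemokine CCL4 (2.70) completed the 10 largest. After RRM1, the largest falls were in the phospholipase PLA2G4A (log2 -1.68), the integrin ITGA8 (-1.59), ANKRD46 (-1.50) and LAMP2, a lysosomal membrane protein (-1.40). They were followed by SEMA3C (-1.34), the imprinted gene PEG3 (-1.28), PSRC1 (-1.18), ANKRD34C (-1.16) and the long noncoding RNA DLEU2 (-1.12). The LAMP2 value came from 200821_at, and its other probe sets, 203041_s_at and 203042_at, gave log2 differences of 0.10 and 0.31, neither past the threshold.

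In all, 1234 of 7936 genes changed in siRRM1, 652 higher and 582 lower, and 139 of them changed at least 2-fold, 120 higher and 19 lower. With each array centred on its median, the split was 572 higher and 818 lower. At an unadjusted p under 0.05 there were 2587 genes, where 396.8 were due by chance, and the groups did not overlap for 59.3% of genes against 33.3% by chance. The count fell to 505 without scramble replicate 1 (343 higher and 162 lower), 709 without scramble replicate 2 (425 and 284) and 307 without siRRM1 replicate 2 (238 and 69). Without siRRM2 replicate 1 or 2, 382 and 380 were lower.

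The p53 targets rose as a group in siRRM1. Of 32 measured members, 25 rose and 0 fell, and 28 rose when adjusted over the list alone. Their mean log2 change was 1.11 (camera adjusted p = 2.69e-23, and adjusted p = 0.161 with an estimated correlation). Beside GDF15 and CDKN1A, the ubiquitin ligase MDM2 rose by log2 1.23 (SE 0.21, adjusted p = 0.0101). Without siRRM1 replicate 2, 21 of the members rose. Among 27 apoptosis regulators, 7 rose and 0 fell, also 7 when adjusted over the list alone (camera adjusted p = 1.92e-04, and adjusted p = 0.178 with an estimated correlation). They included the death receptor FAS (log2 2.08) and PMAIP1, which encodes the BH3-only protein NOXA (1.80), and both of these also belong to the p53 list.

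Of 44 DNA replication genes, 9 rose and 0 fell in siRRM1, and 15 rose when adjusted over the list alone (camera adjusted p = 8.47e-07, and adjusted p = 0.396 with an estimated correlation). The sliding clamp PCNA rose by log2 0.72 and the helicase subunit MCM5 by 0.45. Of 29 G1/S regulators, 5 rose and 0 fell, with 8 adjusted over the list alone (camera adjusted p = 0.00243, and adjusted p = 0.391 with an estimated correlation), led by the cyclin CCNE2 (1.09) and the transcription factor E2F8 (0.57). Of 39 G2/M and mitosis genes, 10 fell and 0 rose, with 16 adjusted over the list alone (camera adjusted p = 5.20e-05, and adjusted p = 0.582 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, had a log2 change of -0.93 and the kinetochore motor CENPE of -0.90. The proliferation marker MKI67 did not pass the threshold (log2 0.13, adjusted p = 0.342), and of its other probe sets 212023_s_at gave -0.04. Without scramble replicate 1, scramble replicate 2, siRRM1 replicate 1 and siRRM1 replicate 2 in turn, the replication genes that rose numbered 2, 4, 4 and 1, the G1/S regulators 4, 3, 7 and 1, and the mitosis genes that fell 5, 3, 6 and 2.

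Genes of nucleotide supply, repair and chromatin moved both ways in siRRM1. Of 21 genes of deoxyribonucleotide supply, 3 rose and 2 fell, with 4 and 3 adjusted over the list alone (camera adjusted p = 0.952). Thymidine kinase TK1 (log2 0.63) and thymidylate synthase TYMS (0.41) rose, while PPAT, an enzyme of purine synthesis, had a log2 change of -0.49. The other fall was RRM1 (-2.63), the target of the siRNA itself, which is a member of the list. Of 30 DNA damage and repair genes, 5 rose and 3 fell, with 6 and 4 adjusted over the list alone (camera adjusted p = 0.309), among them FANCI (0.81) and BRCA1 (0.69) on one side and MDC1 (-0.54) and HUS1 (-0.40) on the other. Of 14 replication-dependent histones, 4 rose and 2 fell, with 5 and 2 adjusted over the list alone (camera adjusted p = 0.0644). H2BC21 (0.84) and H2AC17 (0.80) were higher and the linker histones H1-3 (-0.86) and H1-2 (-0.72) lower. Histone genes have near-identical copies, so the probe sets may not separate them. Leaving out arrays moved these counts. Without siRRM1 replicate 2, 0 repair genes and 0 nucleotide supply genes rose, and without scramble replicate 1 these were 1 and 0. Without scramble replicate 2, 3 repair genes and 1 nucleotide supply gene rose, and 3 and 2 without siRRM2 replicate 1 or without siRRM2 replicate 2. Without scramble replicate 2 or siRRM1 replicate 1, 1 histone rose.

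Of 16 NF-kappaB targets, 9 rose and 1 fell in siRRM1, with 10 and 1 adjusted over the list alone (camera adjusted p = 5.20e-05, and adjusted p = 0.178 with an estimated correlation). CCL4 (log2 2.70) and TNFAIP3, a feedback inhibitor of the pathway (1.54), rose, and REL, which encodes a subunit of the factor itself, had a log2 change of -0.996. Of 21 interferon response genes, 5 rose and 1 fell, with 6 and 1 adjusted over the list alone (camera adjusted p = 0.00317, and adjusted p = 0.391 with an estimated correlation). ISG15 (0.81) and OAS1 (0.79) rose and ISG20 (-0.45) fell. Of 21 immediate early and heat shock genes, 6 rose and 2 fell, with 7 and 2 adjusted over the list alone (camera adjusted p = 0.0219, and adjusted p = 0.543 with an estimated correlation), led by ATF3 (2.10) and IER5 (0.95), with BAG3 (-0.44) and DUSP2 (-0.42) lower. That list's call was lost without scramble replicate 1 or siRRM1 replicate 2. Without siRRM1 replicate 2, 4 NF-kappaB targets, 3 interferon genes and 2 immediate early genes rose. Without scramble replicate 1, 3 interferon genes and 4 immediate early genes rose.

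Of 30 MYC and nucleolar targets, 8 fell and 0 rose in siRRM1, with 11 adjusted over the list alone (camera adjusted p = 3.66e-06, and adjusted p = 0.178 with an estimated correlation), including WDR74 (log2 -0.58) and the helicase DDX10 (-0.46). MYC itself had a log2 difference of -0.14 (adjusted p = 0.599). Without scramble replicate 1, scramble replicate 2 and siRRM1 replicate 2 in turn, 2, 4 and 0 of these members fell. Of 25 chaperones and unfolded protein response genes, 2 fell and 0 rose, and 0 passed when adjusted over the list alone (camera adjusted p = 0.0196, and adjusted p = 0.391 with an estimated correlation). These were PDIA3 (-0.38) and HYOU1 (-0.33), which assist protein folding. Without scramble replicate 1, siRRM1 replicate 2, siRRM2 replicate 1 or siRRM2 replicate 2, 0 of the members fell, without scramble replicate 2 there was 1, and the list's call was lost without siRRM1 replicate 2. Of 28 plasma cell and myeloma genes, 2 rose and 3 fell, with 2 and 6 adjusted over the list alone (camera adjusted p = 0.186). The transcription factor MAF (0.64) and CD79B (0.48) rose, while CAV1 (-0.58) and the receptor kinase FGFR3 (-0.54) fell.

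The remaining lists in siRRM1 follow, to be read beside the 1234 of 7936 genes called there. In the ATF4 stress response 4 of 26 members rose and 1 fell (camera adjusted p = 0.186), with ATF3 (log2 2.10) and DDIT3 (1.35) up and XPOT (-0.44) down. In cholesterol synthesis 1 of 23 rose, TM7SF2 (0.38), and 2 fell, HMGCS1 (-0.54) and MSMO1 (-0.48). In glycolysis 1 of 27 fell, HK2 (-0.56), whose other probe set gave 0.28. Adjusted over the list alone, these counts were 4 and 1 in the ATF4 response, 2 and 3 in cholesterol synthesis and 0 and 1 in glycolysis. Under limma 0 of 33 oxidative phosphorylation genes, 0 of 19 ribosomal protein genes and 0 of 12 reference genes changed, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 1, 2 and 2. Markers of other cell types were mixed. All 3 myeloid markers tested rose, S100A8, S100A9 (2.55) and CSF1R (1.503, named after its value was seen), with camera adjusted p = 0.00269, and adjusted p = 0.391 with an estimated correlation. Of 5 stromal markers, ACTA2 (2.10) and FN1 (0.37) rose, of 3 T cell markers TRBC1 (1.09) rose, and under limma 0 of 4 epithelial markers passed, also 0 at an unadjusted p under 0.05. Adjusted over the list alone, the counts of these markers were the same. Without siRRM1 replicate 2, 1 myeloid marker and 1 stromal marker rose.

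The comparison of siRRM2 with scramble asked the same of the small subunit. GZMB rose 8.55-fold (log2 3.10, SE 0.50, adjusted p = 0.0275) and IL10 rose 6.07-fold (log2 2.60, SE 0.22, adjusted p = 0.00408). CDKN1A rose 4.25-fold (log2 2.09, SE 0.15, adjusted p = 0.00306). The other large rises were HSD11B1, an enzyme of glucocorticoid metabolism (log2 2.23), IL17A (2.04), LAPTM5 (1.87), the TNF family ligand TNFSF9 (1.78), the chemokine CCL1 (1.74), the Fc receptor FCGR2B (1.74) and GNLY, a cytotoxic granule protein (1.68). Below RRM2, the falls were smaller. They were led by SEMA3C (-1.03), the lysosomal galactosidase GALC (-0.997), ANKRD34C (-0.94), SNAPC3 (-0.89), DEPDC1 (-0.84), DLEU2 (-0.82), the circadian receptor NR1D2 (-0.81), FPGT (-0.80) and TBC1D30 (-0.80). GZMB lost its call without scramble replicate 1, scramble replicate 2 or siRRM2 replicate 2.

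In all, 200 genes changed in siRRM2, 159 higher and 41 lower, and 30 changed at least 2-fold, 28 higher and 2 lower. At an unadjusted p under 0.05 there were 1616 genes, and the groups did not overlap for 54.7% of genes against 33.3% by chance. The count fell to 36 without scramble replicate 1, 51 without scramble replicate 2, 35 without siRRM2 replicate 1 and 13 without siRRM2 replicate 2. The 2-fold count fell to 13 without siRRM2 replicate 2. With a trend in eBayes, 336 genes changed.

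The p53 targets rose in siRRM2 as well. Of 32 members, 15 rose and 0 fell, and 22 rose when adjusted over the list alone, with a mean log2 change of 0.58 (camera adjusted p = 2.80e-17, and adjusted p = 0.196 with an estimated correlation). FAS rose by log2 1.32 (SE 0.11, adjusted p = 0.00408), and MDM2 had a log2 difference of 0.88 that did not pass (SE 0.21, adjusted p = 0.0750). Without scramble replicate 1, scramble replicate 2, siRRM2 replicate 1 and siRRM2 replicate 2 in turn, 6, 5, 6 and 2 of the members rose. Of 27 apoptosis regulators, 4 rose and 0 fell, with 6 adjusted over the list alone (camera adjusted p = 0.00122, and adjusted p = 0.233 with an estimated correlation). The anti-apoptotic gene BCL2 was among them (0.82), and its other probe sets gave 0.29 and -0.07. Without the same arrays in turn, 2, 1, 2 and 1 of these regulators rose.

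Of 21 interferon response genes, 5 rose and 0 fell in siRRM2, with 11 adjusted over the list alone (camera adjusted p = 8.79e-07, and adjusted p = 0.196 with an estimated correlation). The regulator IRF7 (log2 0.73) and IFI27 (0.67) led. Of 16 NF-kappaB targets, 3 rose and 0 fell, with 5 adjusted over the list alone (camera adjusted p = 4.07e-04, and adjusted p = 0.196 with an estimated correlation), CCL4 (1.61) and TNFAIP3 (0.86) among them. Of 39 G2/M and mitosis genes, CENPE (-0.70) and CDC20 (-0.61) fell and 0 rose, with 4 lower when adjusted over the list alone (camera adjusted p = 2.21e-06, and adjusted p = 0.649 with an estimated correlation). Without scramble replicate 1, siRRM2 replicate 1 or siRRM2 replicate 2, 0 members of these lists passed. Without scramble replicate 2, 2 interferon genes, 1 NF-kappaB target and 0 mitosis genes passed. Without siRRM1 replicate 1 or 2, 1 mitosis gene passed. MKI67 did not pass in siRRM2 (log2 0.16, adjusted p = 0.363).

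Other lists showed few calls in siRRM2, where 200 of 7936 genes were called. The MYC and nucleolar targets were lower as a group (camera adjusted p = 0.00147, and adjusted p = 0.337 with an estimated correlation), with 0 of 30 members past the threshold, over all genes or adjusted over the list alone, and 3 at an unadjusted p under 0.05. MYC had a log2 difference of 0.25 (adjusted p = 0.434). Of 14 histones, H2BC5 rose (0.83) and H1-3 fell (-0.71), with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0191, and adjusted p = 0.649 with an estimated correlation). The myeloid list was called (camera adjusted p = 0.0176, and adjusted p = 0.579 with an estimated correlation) with 0 of 3 members past the threshold, and S100A8 (log2 2.94, adjusted p = 0.0526) and S100A9 (1.39, adjusted p = 0.127) missed it. Adjusted over the list alone, 2 myeloid markers rose. Single members rose in the plasma cell (MAF, 0.58), immediate early (IER5, 0.46), T cell (TRBC1, 0.64) and stromal (ACTA2, 1.31) lists, and RRM2 alone passed in the deoxyribonucleotide list, where 2 members fell when adjusted over the list alone. In the stromal list 1 rose and 1 fell by that adjustment. Under limma 0 members changed in the DNA replication, G1/S, repair, unfolded protein, ATF4, cholesterol, glycolysis, oxidative phosphorylation, ribosomal, reference and epithelial lists. At an unadjusted p under 0.05 these lists held 1, 6, 6, 2, 4, 8, 4, 1, 0, 2 and 0. Adjusted over the list alone, 3 G1/S regulators rose, 2 cholesterol genes rose and 2 fell, and 4 immediate early genes rose. Values there included PCNA at log2 0.34 (adjusted p = 0.0952) and CCNE2 at 0.52 (adjusted p = 0.0652).

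**Figure D2:**
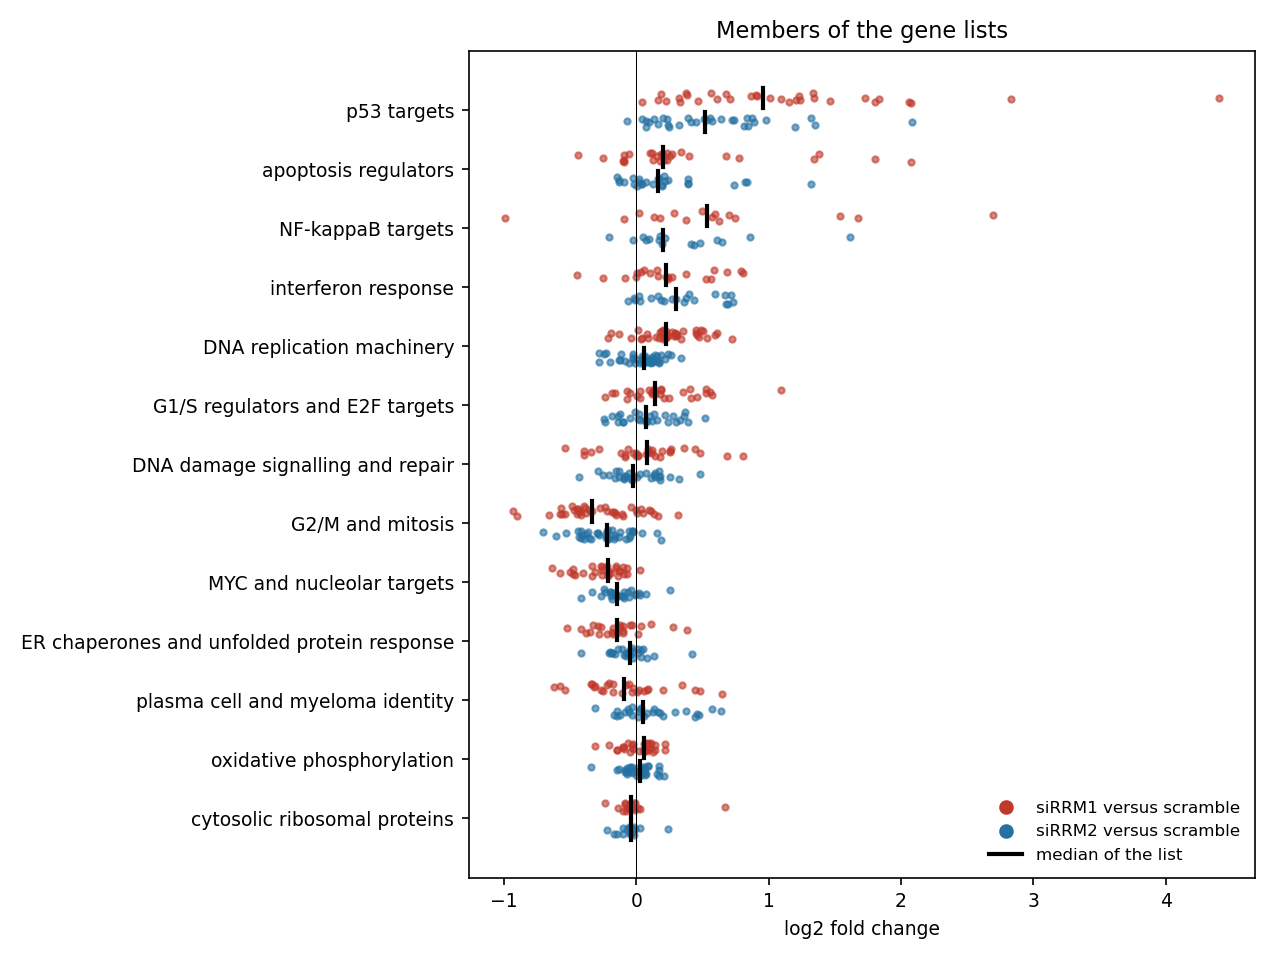
Log2 fold change of the members of 13 gene lists against scramble, with 1 point per gene, siRRM1 in red and siRRM2 in blue, and black bars for list medians. The p53 targets had medians of 0.96 and 0.52, and the G2/M list had medians of -0.34 and -0.22.

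The changes in both knockdowns ran in parallel across genes. Their log2 fold changes correlated at r = 0.867 (jackknife SE 0.0751 over arrays) and rho = 0.831. Unchanged groups simulated against the shared scramble arrays gave means of 0.503 and 0.479. The covariance was 0.0791 against a simulated 0.00726, a difference of 0.0719. Genes called higher in both numbered 150 and lower in both 37, and 0 were called in opposite directions. These were 34, 44, 33 and 10 higher and 1, 5, 1 and 2 lower without scramble replicate 1, scramble replicate 2, siRRM2 replicate 1 and siRRM2 replicate 2 in turn, and 22 were lower without siRRM1 replicate 2. Independent lists would share 13.1 and 3.01. Part of the excess may come from the shared controls, because 2 scramble arrays cannot be divided so that each part keeps replicates. Of the 200 genes called in siRRM2, 187 were also called in siRRM1, 199 had the same direction there and 147 (73.5%) had the larger change there. The p53 targets that rose in both knockdowns numbered 15.

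**Figure D3:**
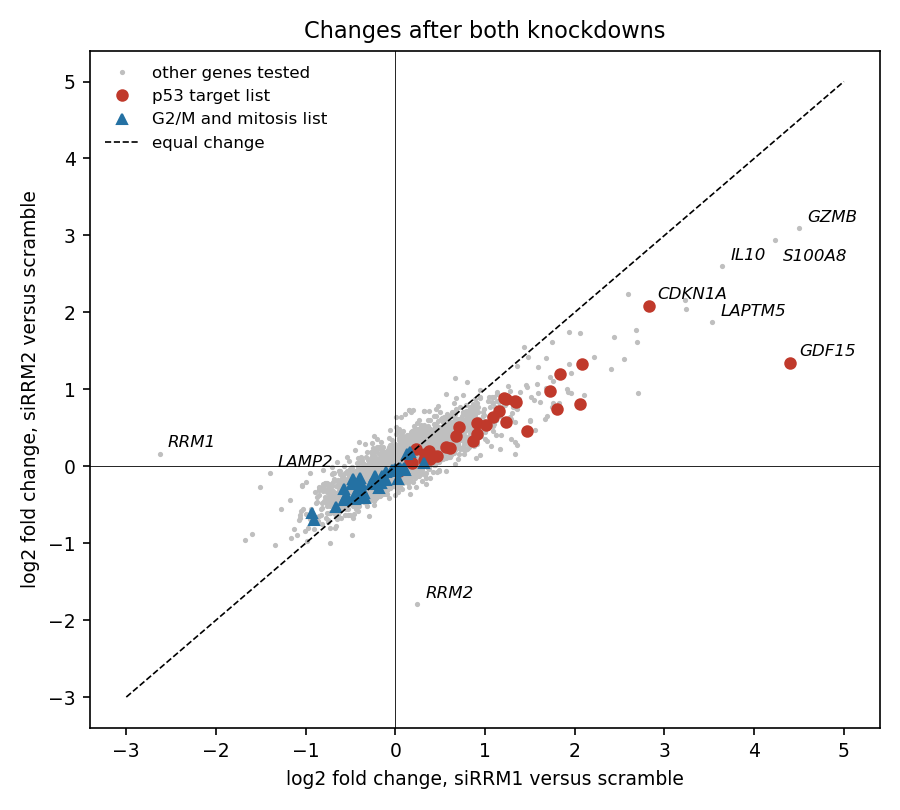
Log2 fold change against scramble in siRRM1 (horizontal) and siRRM2 (vertical) for the 7936 genes tested, with p53 targets as red circles, G2/M and mitosis genes as blue triangles and a dashed line of equal change. GDF15 lay far from the line (4.40 and 1.35), as did RRM1 and RRM2, the siRNA targets.

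The direct comparison of siRRM1 with siRRM2 asked where the responses differed. GDF15 was 8.32-fold higher in siRRM1 (log2 3.06, SE 0.19, adjusted p = 0.00258). LAPTM5 (log2 1.66), the polo-like kinase PLK2 (1.24) and PMAIP1 (1.06) were also higher, and RRM2, the target of the other siRNA, was higher by 2.03. Lower in siRRM1 were RRM1 (-2.79), LAMP2 (-1.32) and PSRC1 (-0.74). The LAMP2 difference lay in 200821_at, while its other probe sets gave -0.03 and -0.05. CDKN1A (log2 0.74, adjusted p = 0.144), MDM2 (0.36, adjusted p = 0.621), MYC (-0.39, adjusted p = 0.477) and MKI67 (-0.02, adjusted p = 0.954) did not pass.

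In total 13 genes differed between the knockdowns, 10 higher and 3 lower in siRRM1, and 8 by at least 2-fold. At an unadjusted p under 0.05 there were 797 genes, and the groups did not overlap for 40.8% of genes against 33.3% by chance. The count was 4 without siRRM1 replicate 1, 2 without siRRM1 replicate 2, 3 without siRRM2 replicate 1 and 6 without siRRM2 replicate 2. PLK2 lost its call in each of these, LAPTM5 and PMAIP1 lost theirs without either siRRM1 replicate or siRRM2 replicate 1, and LAMP2 lost it without siRRM1 replicate 2 or with the mean of its probe sets.

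The p53 targets were higher in siRRM1 than in siRRM2 by a mean log2 of 0.53 (camera adjusted p = 9.63e-28, and adjusted p = 0.125 with an estimated correlation). The difference was above 0 for 31 of 32 members, 3 passed the threshold, and 24 passed when adjusted over the list alone. The DNA replication genes were higher by a mean of 0.21 (camera adjusted p = 4.30e-13, and adjusted p = 0.327 with an estimated correlation) and the G1/S regulators by 0.12 (camera adjusted p = 2.87e-04, and adjusted p = 0.327 with an estimated correlation), with 0 members past the threshold and 0 and 1 adjusted over the list alone. At an unadjusted p under 0.05 there were 16 and 4. The plasma cell and myeloma genes were lower in siRRM1 by a mean log2 of -0.19, below 0 for 22 of 28 members (camera adjusted p = 5.00e-06, and adjusted p = 0.161 with an estimated correlation), with 0 past the threshold, 2 lower adjusted over the list alone and 10 lower at an unadjusted p under 0.05. MYC and nucleolar targets were lower by a mean of -0.14 (camera adjusted p = 1.12e-04, and adjusted p = 0.217 with an estimated correlation), with 0 members past the threshold, over all genes or adjusted over the list alone, and 7 at an unadjusted p under 0.05. Apoptosis regulators (camera adjusted p = 9.61e-04) and NF-kappaB targets (camera adjusted p = 0.00209) were higher, each with an adjusted p = 0.217 with an estimated correlation. Over all genes 1 and 0 of their members passed, and adjusted over the list alone 5 rose in each while 0 and 1 fell. The ATF4 (camera adjusted p = 0.00556, and adjusted p = 0.420 with an estimated correlation), immediate early (0.0245 and 0.539), myeloid (0.00474 and 0.373), stromal (0.0330 and 0.356) and repair (0.0330 and 0.624) lists were called higher, and the unfolded protein list lower (0.0156 and 0.371). These 6 lists held 0 members past the threshold under limma, and 4, 5, 2, 2, 6 and 2 at an unadjusted p under 0.05. Adjusted over the list alone, 3, 2, 2, 1, 0 and 0 rose and 0 fell, and all 6 lost the call without siRRM1 replicate 2. The interferon list did not differ past the threshold (camera adjusted p = 0.176), nor did the G2/M list (camera adjusted p = 0.258).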

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

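The fit described here was chosen only after the data were seen. Probe sets with no single gene name lay outside the gene comparisons, and 1572 of them were bright enough to test. Of these, 120 differed between siRRM1 and scramble, 62 higher and 58 lower, and 2 differed between siRRM2 and scramble, both higher. They drew attention because they are signals in data that the comparisons of genes do not use. Among them, a probe set shared by most histone H4 genes, 205967_at, had a log2 change of -1.14 in siRRM1 (adjusted p = 0.0168) and -0.64 in siRRM2, where it did not pass. A probe set shared by 6 histone H2A genes, 207156_at, rose by log2 1.59 in siRRM1 (adjusted p = 0.00642). Both were picked after their values were seen.

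Of 58 control probe sets tested, 1 differed in siRRM1. This was AFFX-M27830_5_at, a control for ribosomal RNA, which was higher by log2 0.72, and 0 of the control probe sets differed in siRRM2.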

How the results depend on the processing

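Every setting here was planned. The knockdown of RRM1 kept its direction and its call under every alternative, with log2 values of -3.10 to -2.16 when arrays were left out. RRM2 kept its direction (-2.24 to -1.34) and lost its call without scramble replicate 1 (-1.79) or replicate 2 (-1.78). The correlation between knockdowns ranged from 0.782, without siRRM2 replicate 2, to 0.889. Leaving out arrays gave 307 to 1222 genes in siRRM1 against scramble, 13 to 203 in siRRM2 and 2 to 16 between the knockdowns, where the reported counts were 1234, 200 and 13. For changes of at least 2-fold the ranges were 100 to 184, 13 to 35 and 2 to 11, against 139, 30 and 8. An arm left with 1 array is assumed to vary like the other groups.

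At an adjusted p under 0.01 the counts were 329, 15 and 2, and at 0.1 they were 1980, 519 and 45, by construction. At least 2-fold and under 0.01 gave 11 in siRRM2 and 2 between knockdowns. A trend in eBayes gave 336 in siRRM2 and 42 between knockdowns. The 60th percentile filter, which tests fewer genes, gave 91 genes of at least 2-fold in siRRM1 and 4 between knockdowns, with or without the 2-fold limit. Every probe set by itself gave 5 between knockdowns, also with the limit. For the others the cause was not tested. Of the 200 genes called in siRRM2, 198 kept their call with the trend.

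The replicate number as a block gave 1904, 622 and 153 genes, 26 of at least 2-fold between knockdowns, and 378 higher and 173 lower in both. Replicate differences correlated at 0.382 for scramble and siRRM1, 0.363 for scramble and siRRM2 and 0.210 for siRRM1 and siRRM2, but with 2 arrays per group the numbers are not taken as pairs. Pseudocounts were not run because the values are already on a log scale. Over all alternatives together, 0 results on lists and named genes reversed, 78 list results and 260 gene results lost their call and 38 and 49 gained one. Dim genes were tested only in the fit without the filter, which gave 1130, 171 and 14 genes.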

Other observations

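The leukocyte gene lists, the tests for foreign cells, for a deviation of the scramble arrays and for completeness of the knockdown, the tests of RNA quality by control transcripts and by counts of genes, and the test of p53 targets between the siRRM1 replicates were chosen only after the results were seen. The test for foreign cells was run in 3 forms, and the rules for reading it, the scramble test and the control transcripts, and the value used for RNA quality in the leukocyte set, were changed after their values were known. The other tests were set beforehand.

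A set of 21 leukocyte transcripts, not all of them particular to other blood cells, was picked because its members rose. It therefore does not show how such transcripts behave in general. It held granule genes of cytotoxic cells (GZMB, GNLY, NKG7, PRF1), myeloid genes (S100A8, S100A9, CSF1R, C3AR1), cytokines (IL10, IL17A, CCL1, CCL4) and the tyrosine phosphatase PTPRC. Its median log2 change was 2.06 in siRRM1 and 1.61 in siRRM2, where 14 of the 21 passed the threshold.

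Foreign blood cells could be a cause and cannot be told apart from a response in the myeloma cells, although they would bring all their abundant transcripts. In the fit without the filter on dim genes and with the called genes included, 18 of 30 transcripts of monocytes and 16 of 29 of T cells and NK cells (a share of 0.552) stayed below a log2 change of 1 in siRRM1 by more than 2 SE, such as LYZ (0.16), CD14 (-0.002), CD3D (0.014) and CCL5 (0.06). Of these flat transcripts 15 and 14 lay below the signal at which genes were tested, so they decide little. Medians, the earlier forms, were 0.30 and 0.42 over these lists, and 0.13 over 18 and 0.06 over 19 without the picked genes. In the shorter lists FCER1G (0.72), TRBC1 (1.09), CD52 (1.08), IL32 (0.68) and CD69 (0.42) rose past the threshold of that fit; all genes here were named after their values were seen.

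Poor RNA in siRRM1 replicate 2 is argued against by the other knockdown arrays. The set's median was 1.61 in siRRM2 and 2.00 in siRRM1 without that array, although its members were picked because they rose. A deviation of the scramble arrays alone stays open. It would not give the differences between the knockdowns of LAPTM5 (1.66) and TNFSF9 (0.91), which were called over all genes. LAPTM5 lost that call without either siRRM1 replicate or siRRM2 replicate 1, though its signals did not overlap (8.47 and 8.90 in siRRM1, 6.78 and 7.27 in siRRM2). TNFSF9 was not followed through the alternatives. Both were picked, like the other members, because they rose, so they cannot decide for the set. The mean difference of 0.74 over the 14 members called in siRRM2 cannot either, because it comes from genes picked for high siRRM1 values. A response to the knockdowns or to the siRNA sequences stays open as well.

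The siRRM2 response was smaller, with p53 targets at 0.52 of their siRRM1 mean. For these targets RNA quality of siRRM1 replicate 2 is argued against by the difference between knockdowns, which was log2 0.52 without that array (SE 0.04) and 0.53 with it. For the counts of genes it stays open. The ratio of the siRRM1 to the siRRM2 count was 1.51 without that array, against 6.17 with all arrays. That fit keeps 1 array in siRRM1 against 2 in siRRM2. Leaving out siRRM1 replicate 1 instead also keeps 1 array, and the siRRM1 count then stayed close to that with all arrays. Having 1 array is therefore not enough to explain the fall. The ratio cannot decide, because poor RNA in replicate 2 and a larger response there would both give it. A less complete loss of RRM2 could be the cause and cannot be told apart from a difference between the subunits. The share of transcript left was 12.8% to 39.6% for RRM2 and 11.1% to 24.3% for RRM1, depending on array and probe set, and the lowest RRM2 share minus the highest RRM1 share was -11.5 percentage points.

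SiRRM1 replicate 2 departed further from scramble than replicate 1. A larger response to the knockdown may contribute. Less RRM1 was left in replicate 2, 11.7% (201477_s_at) and 11.1% (201476_s_at) of the scramble mean, against 22.4% and 24.3% in replicate 1. The excess of replicate 2 over replicate 1 rose with the siRRM2 fold change across genes. The slope was 0.26 against 0.12 for the scramble replicates. For the p53 targets the difference between the replicates was 0.019 (SE 0.051), where that slope would give 0.15. This cannot decide for their part. The SE rests on the replicate pairs of scramble and siRRM2 alone, and the scramble replicates had a slope of their own. RNA quality stays open, because the control transcripts disagree. Their median difference between 3′ and 5′ signal lay 0.29 log2 above the highest other array and 7 of 9 lay above it, but GAPDH did so by 0.004, and ACTB (-0.018) and 1 lys spike set (-0.029) lay below it.

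The LAMP2 difference was specific to 1 of its probe sets and to siRRM1, with log2 changes of -1.40 in siRRM1 and -0.09 in siRRM2 for 200821_at.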
